A study of Mus musculus with 8 samples.

How the data were processed

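RNA was measured in mouse embryonic stem cells with a conditional Ino80 allele, in 8 libraries: 2 labelled knockout and 2 labelled wild type in the naive state and the same in the primed state. Per the labels' protocols, naive cells were grown with inhibitors of MEK and GSK3 and with LIF, and primed cells with FGF2, Activin A and the tankyrase inhibitor XAV939. Deletion was induced with 100 nM 4-OHT for 2 days, followed by 2 more days, per the labels' protocols. Whether the wild-type libraries came from cells given 4-OHT is not given in the sources used here. ERCC spike-in RNA was added to the lysate, and libraries of total RNA were made after removal of ribosomal RNA, per the labels' protocols. The tools cutadapt 1.9, STAR 2.5.2b, featureCounts 1.5.1 and affy and the genome build mm9 are named per the submitters' processing notes, without parameters or the strand counted.

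Each file holds 24505 rows with 1 RPKM value per gene, and the deposited RPKM values had been scaled further by the authors by an unstated method. The scaling was read from the values: no value is 0, and genes tied in 1 library are tied in all 4 libraries of its state but not in the other state. In the scaled values, naive wild-type replicates differ by a median log2 of 0.84 among weakly and -0.14 among strongly expressed genes. Whether the scaling itself depends on the level cannot be told without unscaled values. The naive and primed libraries were scaled apart, so they were not tested against each other, although that comparison had been planned. The files hold 0 spike-in rows, so no absolute scale could be set. The authors may have scaled on the spike-ins, which is not stated, so the main tests used the values as deposited. Names that a spreadsheet had turned into dates (26 rows, 19 of them tested) were tested but not named. Of all names, 24051 match a reference symbol, 347 an older symbol only and 107 neither. Sequencing depth cannot be had from these values.

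Values were taken as log2(RPKM + 1), and genes with at least 1 RPKM in at least 2 libraries were tested, 13428 in all. A linear model with 4 group means was fitted over the 8 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the moderated variance, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison at a threshold of 0.05. The 3 comparisons tested were knockout against wild type in each state and the difference of these effects, primed minus naive. As deposited, limma put the prior degrees of freedom at infinity beside 4 residual ones, with a median residual SD of 0.179. Every gene then takes its variance from the trend alone, which makes the adjusted p of large changes very small. After quantile normalization the prior degrees of freedom were 3.71 and the median residual SD 0.0478, and these results are given beside the deposited ones. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

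Sets of genes were tested with limma's camera at a preset correlation of 0.01 between genes, on 41 lists, each with at least 5 tested members, and adjusted over the 41 lists. Camera with an estimated correlation and fry were run as alternatives. Counts of called members are given from the adjustment over all genes and over the list alone. The lists, the comparisons, the alternatives except 1 and the rule for the genes to be named were written before the data were examined. The rule has 3 parts. It takes Ino80 and 19 markers of state and lineage. It adds at least 5 genes per direction from the top of the order by fold change, among called genes whose groups do not overlap and whose higher group has a mean of at least 5 RPKM. From each list described it adds up to 2 called members per direction. Genes without a proper name were skipped, and some genes that the rule selects are not reported here.

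The procedure was tested on simulated data of 13428 genes with the same design. Of genes raised or lowered 1.5-fold, 2-fold and 4-fold it called 17 of 67, 50 of 67 and 63 of 66 in the naive comparison, 20, 47 and 60 in the primed comparison and 10, 27 and 56 in the difference. Of 13228 unchanged genes it called 4, 3 and 3. The simulated noise was independent between genes and libraries, without the shifts of whole libraries seen in the deposited values. These counts therefore do not give the rate of false calls in the deposited data. The alternatives were a pseudocount of 0.1, no filter and a filter of 5 RPKM, median centring, quantile normalization, each state alone, variances without a trend, library weights, the replicate number as a term, and leaving out each library in turn. In the last case the lone library of a group is assumed to vary like the other groups. Loess normalization within each state was added after the data were seen.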

Results

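RNA was sequenced from mouse embryonic stem cells that carry a conditional allele of Ino80, the gene of the ATPase of the INO80 chromatin remodelling complex. The cells were kept either in the naive state, in medium with inhibitors of MEK and GSK3 and the cytokine LIF, or in the primed state, in medium with FGF2, Activin A and the tankyrase inhibitor XAV939. Each state had 2 libraries labelled wild type and 2 labelled knockout, 8 libraries in all. The series title names bivalency, the joint presence of activating and repressive histone marks at promoters. Its design text asks how loss of INO80 affects the transcriptome in both states. The comparisons were knockout against wild type within each state and the difference between those effects. The deposited RPKM values of one library summed to between 341480.0 and 507598, which is not a read depth. The depth of the libraries is unknown. Means are given in RPKM ± SD of 2 libraries, and changes as differences of log2(RPKM + 1) ± SE, knockout minus wild type. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

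As deposited, Ino80 itself was called lower in the primed but not in the naive libraries labelled knockout. In the naive state Ino80 stood at 15.9 and 15.1 RPKM in the 2 libraries labelled knockout and at 17.0 and 14.5 in the wild-type libraries, a difference of -0.020 ± 0.18 that did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.975). For the primed state the values were 9.12 and 8.74 RPKM against 15.9 and 20.3, a change of -0.93 ± 0.18 (limma adjusted p = 2.0e-06), or -0.26 after quantile normalization (adjusted p = 2.3e-04). One value per gene also counts exons outside a deleted part, so this level is a weak check of the labels, and below the naive libraries are called labelled knockout. An incomplete deletion in the naive libraries would leave such values too. Most of the primed fall goes with that of all genes, whose median was -0.53, or -0.78 in log2 RPKM among genes with a mean log2 RPKM of 2 to 4, the range of Ino80, and -0.28 was left after loess normalization. The check is thus weak in the primed state as well, an incomplete deletion is not excluded there either, and primed knockout below is the name in the labels. After loess normalization the naive difference was -0.099 and passed (adjusted p = 0.0461), and with median centring the difference between the states, -0.16, did not (adjusted p = 0.214).

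**Figure D1:**
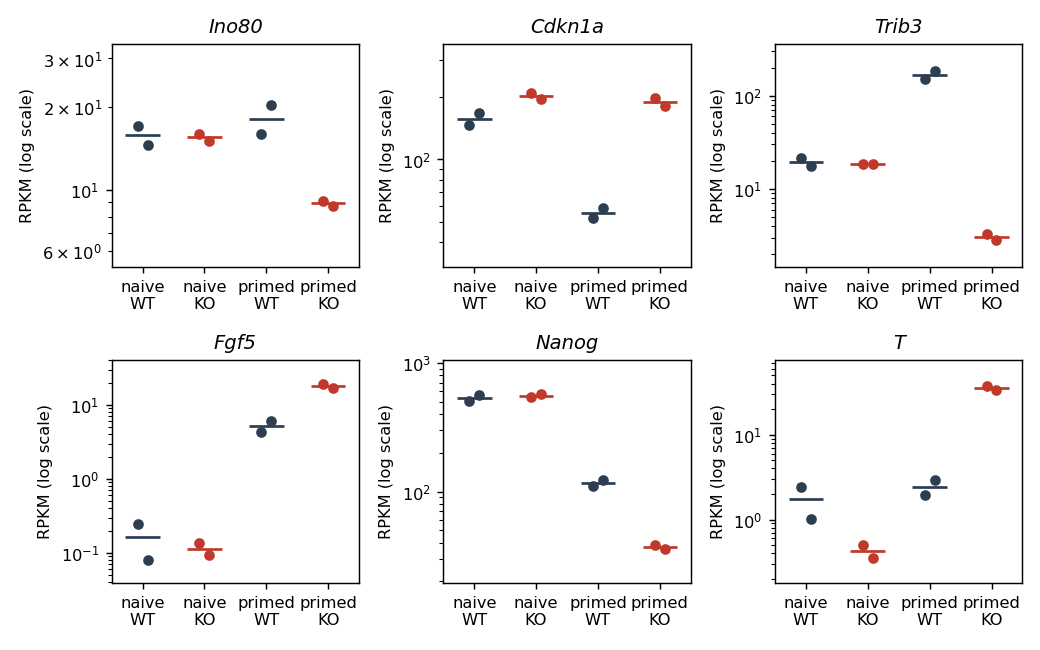
RPKM on a log axis of Ino80 and 5 genes named in the text in each of the 8 libraries, with wild-type libraries in blue, libraries labelled knockout in red and a bar at each group mean. Ino80 was lower in the primed knockout libraries and overlapped between genotypes in the naive state, while Trib3 and Nanog were lower and T and Fgf5 higher in the primed knockout libraries.

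In the naive libraries labelled knockout, targets of the tumour suppressor p53 rose and genes of cholesterol synthesis fell. Of 25 p53 targets tested, 21 were higher and 0 lower, and the same 21 and 0 when adjusted over the list alone, with a median difference of 0.73. Pmaip1, which encodes the cell-death protein Noxa, stood at 14.4 ± 0.402 against 5.51 ± 1.23 RPKM and Ddit4l at 25.3 ± 0.0702 against 10.7 ± 2.03, and Cdkn1a, the gene of the cell-cycle inhibitor p21, at 203 ± 9.64 against 157 ± 13.9. Of 24 genes of cholesterol synthesis, 15 were lower and 0 higher, 17 and 0 when adjusted over the list alone, with a median of -0.56. Mvd fell to 30.4 ± 0.571 against 67.2 ± 0.842 RPKM and Nsdhl, another enzyme of the pathway, to 15.9 ± 0.287 against 33.8 ± 0.688. Both lists passed camera with a preset correlation (adjusted p = 9.3e-29 and 3.7e-23), but neither did with an estimated one (adjusted p = 0.995 with an estimated correlation for both). After quantile normalization 23 p53 targets were higher and 1 lower, with a median of 0.68, and all 24 cholesterol genes were lower, with a median of -0.58. The Cdkn1a call did not hold without naive knockout replicate 1 (limma adjusted p = 0.148).

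Genes of the integrated stress response, which ATF4 and CHOP raise, went both ways in the naive state. Of 22 tested, 10 were lower and 3 higher, 11 and 3 when adjusted over the list alone, with a median of -0.29 (camera adjusted p = 2.5e-04 and adjusted p = 0.995 with an estimated correlation). Nupr1, a stress-induced chromatin protein, fell to 9.15 ± 0.891 against 35.0 ± 1.902 RPKM, while Sesn2, which p53 also raises, rose to 99.5 ± 1.89 against 59.5 ± 3.87. Sesn2 is also among the p53 targets tested, so the counts of the lists are not independent. Stc2 stood at 3.10 ± 0.225 against 5.95 ± 1.95 RPKM and Atf3 at 6.34 ± 0.344 against 3.26 ± 0.889, calls that ended without a naive knockout library (limma adjusted p = 0.237 for Stc2 without replicate 2 and 0.258 for Atf3 without replicate 1). Among genes of both pluripotent states, 8 of 20 rose and 1 fell, the same when adjusted over the list alone, with a median of 0.27 (camera adjusted p = 1.7e-04 and adjusted p = 0.995 with an estimated correlation). Utf1, a chromatin protein of pluripotent cells, rose to 79.9 ± 8.87 against 44.8 ± 6.32 RPKM and Lin28a, an RNA-binding protein, fell to 5.46 ± 0.0449 against 9.49 ± 1.97. Quantile normalization gave 4 and 14 called higher and lower for the stress response and 14 and 2 for this list, with medians of -0.31 and 0.28. The list of shared genes passed neither without naive wild-type replicate 1 (camera adjusted p = 0.128) nor with median centring (camera adjusted p = 0.11).

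Ribosomal protein and respiratory chain genes were lower by small amounts in the naive libraries labelled knockout. Of 75 ribosomal protein genes, 32 fell and 2 rose, 38 and 2 when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 1.3e-23 and adjusted p = 0.995 with an estimated correlation). Rpl37a fell to 238 ± 21.5 against 402 ± 23.8 RPKM. These genes have many processed pseudogenes, so the sharing of reads makes their values uncertain. Of 76 genes of oxidative phosphorylation, 27 fell and 7 rose, 31 and 10 when adjusted over the list alone, with a median of -0.11 (camera adjusted p = 3.4e-10 and adjusted p = 0.995 with an estimated correlation). Ndufa13 and Ndufa2, both of complex I, fell to 24.6 ± 1.43 against 71.3 ± 0.792 and to 31.9 ± 1.99 against 74.0 ± 1.19 RPKM. After quantile normalization 37 ribosomal protein genes fell and 16 rose, with a median of -0.082, and 35 genes of oxidative phosphorylation fell and 17 rose, with a median of -0.091. Without naive wild-type replicate 2 the ribosomal median was -0.11 and the oxidative phosphorylation median -0.061, which no longer passed (camera adjusted p = 0.143). Without naive wild-type replicate 1 the oxidative phosphorylation median was -0.18, without naive knockout replicate 2 it was -0.068, and with median centring the ribosomal list did not pass (camera adjusted p = 0.22).

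Among genes of DNA repair and replication, 6 of 35 fell and 0 rose, 8 and 0 when adjusted over the list alone, with a median of -0.16 (camera adjusted p = 4.3e-05 and adjusted p = 0.995 with an estimated correlation). Mcm2, a subunit of the replicative helicase, fell to 92.7 ± 1.70 against 187 ± 15.2 RPKM and the replication factor Gins2 to 27.6 ± 0.531 against 52.1 ± 0.546. The list did not pass without naive wild-type replicate 2 (camera adjusted p = 0.0688). After quantile normalization 22 fell and 3 rose, with a median of -0.17. Of 23 Hox genes, 2 were lower and 0 higher, the same over the list alone, with a median of -0.39 (camera adjusted p = 0.00484 and adjusted p = 0.995 with an estimated correlation). The 2 were Hoxc4, at 1.11 ± 0.0503 against 3.31 ± 0.609 RPKM, and Hoxb13, at 0.949 ± 0.0895 against 2.49 ± 1.36, and both calls ended without naive knockout replicate 2 (limma adjusted p = 0.114 and 0.378). After quantile normalization 16 Hox genes were lower and 1 higher, with a median of -0.43. As deposited, the Hox median was -0.15 without naive wild-type replicate 1 and -0.59 without replicate 2.

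The other 6 lists that passed camera in the naive state held few called members. For targets of FGF-ERK signalling 5 of 16 were higher and 0 lower, 6 and 0 over the list alone, among them the feedback inhibitor Spry4 at 5.66 ± 1.08 against 1.44 ± 0.418 RPKM. For surface ectoderm and epithelium the counts were 4 of 17 and 0, and for mesenchymal and matrix genes 6 of 25 and 0, 7 and 0 over the list alone. Fewer members were higher than lower for glycolysis with 0 and 4 of 22, for germline genes with 0 and 5 of 20, and for genes of G2 and mitosis with 0 and 4 of 29, the same counts when adjusted over the list alone. Their camera adjusted p were 5.1e-04, 0.0129, 0.029, 0.00103, 0.0206 and 0.0201 in that order, and for all 6 adjusted p = 0.995 with an estimated correlation. Members called higher and lower after quantile normalization were 8 and 1, 10 and 1, 11 and 5, 6 and 12, 3 and 9, and 2 and 14 in the same order, and the lists of glycolysis, germline genes and mesenchymal and matrix genes no longer passed (camera adjusted p = 0.0687, 0.0687 and 0.264). Leaving out naive wild-type replicate 2 ended the calls of surface ectoderm and of G2 and mitosis (camera adjusted p = 0.0679 and 0.927). Leaving out naive knockout replicate 1 ended those of G2 and mitosis and of mesenchymal genes (0.144 and 0.0558). Leaving out naive wild-type replicate 1 ended that of mesenchymal genes (0.105), and leaving out either primed wild-type replicate ended that of germline genes (0.0552 without replicate 1). With median centring only that of surface ectoderm held (camera adjusted p = 0.0544 for FGF-ERK targets, 0.427 for mesenchymal genes, 0.11 for glycolysis, 0.0824 for germline genes and 0.198 for G2 and mitosis). The germline call also ended with a pseudocount of 0.1 and after loess normalization (0.112 and 0.0998), and that of mesenchymal genes after loess normalization (0.194).

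Among genes chosen by the rule given with the methods, the largest rise in the naive state was that of Ltb4r1, the receptor of leukotriene B4, at 8.11 ± 1.17 against 1.06 ± 0.623 RPKM, a log2 change of 2.17 ± 0.28. Ssc5d rose by 2.13, Ms4a10 by 1.88, Cryab, a small heat shock protein, by 1.80 and Anxa2, a membrane-binding annexin, by 1.70, from 5.19 to 19.01 RPKM. Ltb4r1 lies next to Ltb4r2, and how reads shared by such neighbours were counted is not stated, so its value is uncertain. The largest fall was that of Stra8, which starts meiosis, at 4.13 ± 0.650 against 28.03 ± 2.28 RPKM, a log2 change of -2.50 ± 0.28. Pla2g1b changed by -2.49, the germ-cell factor Sohlh2 by -2.26, Suclg2, a subunit of succinyl-CoA synthetase, by -2.01 and the DNA repair enzyme Parp2 by -1.99, from 21.5 to 4.68 RPKM. Cd3e, between the last 2 in size, fell from 11.4 to 2.08 RPKM. Of these 11 genes Cryab had the largest limma adjusted p, 1.2e-08, and after quantile normalization Anxa2 had the largest, 8.4e-07.

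In all, 1602 of 13428 genes passed at a limma adjusted p under 0.05 in the naive state, 816 higher and 786 lower, of which 100 and 113 changed 2-fold or more. The count depends on single libraries. Without naive knockout replicate 1 it was 552, without naive knockout replicate 2 it was 570, without primed wild-type replicate 1 it was 2946 and without replicate 2 it was 2938. The split was 1427 higher and 595 lower without naive wild-type replicate 1 but 515 and 1207 without replicate 2, and among 2-fold changes 240 and 76 but 55 and 242. After quantile normalization 7967 genes passed, 4280 higher and 3687 lower, among them 811 of the 816 higher and 778 of the 786 lower. The counts at 2-fold or more depend on the pseudocount. As deposited with a pseudocount of 0.1 they were 199 higher and 186 lower.

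Of the markers fixed in advance, only Cdkn1a, given above, Sox2 and T passed in the naive state as deposited. Sox2 stood at 136 ± 3.11 against 112 ± 16.4 RPKM, a rise of 0.29 ± 0.098 (limma adjusted p = 0.0344), and T, the mesoderm factor Brachyury, at 0.428 ± 0.101 against 1.73 ± 1.01, a change of -0.88 ± 0.28 (adjusted p = 0.0186). Each call ended when any 1 of 5 libraries was left out. The adjusted p reached 0.5 for Sox2 without naive knockout replicate 1 and 0.375 for T without naive knockout replicate 2. The change was 0.14 for Sox2 without naive wild-type replicate 2 and -0.49 for T without naive wild-type replicate 1. The core factors Pou5f1 and Nanog, at 694 against 653 and 557 against 536 RPKM, and the naive-state factors Klf4, Zfp42 and Esrrb, at 99.6 against 99.4, 256 against 226 and 199 against 181, did not pass as deposited. Fgf5 at 0.114 against 0.163, Otx2 at 0.363 against 0.297, Dnmt3b at 20.7 against 18.1, Eomes at 6.51 against 6.05, Gata4 at 2.13 against 2.36, Gata6 at 1.65 against 0.693, Sox1 at 1.35 against 1.77, Pax6 at 0.234 against 0.238 and H2afz at 421 against 472 did not pass either, knockout against wild type, and Mixl1 and Sox17 were below the filter. After quantile normalization, whose residual spread was smaller, Nanog (0.26, adjusted p = 1.8e-04) and Gata6 (0.64, adjusted p = 7.3e-04) were among those that did, and the signs of Klf4 and H2afz turned.

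In the primed knockout libraries all 22 genes of the integrated stress response were lower, and so were most genes of glycolysis. Trib3, a pseudokinase raised by ATF4 and CHOP, stood at 3.07 ± 0.315 against 167 ± 22.5 RPKM, Chac1, a glutathione-degrading enzyme, at 1.43 ± 0.0348 against 83.6 ± 13.7 and Nupr1 at 0.402 ± 0.0414 against 25.5 ± 4.48. The list's median was -2.49, or -1.95 relative to all genes, and 22 fell and 0 rose both over all genes and over the list alone (camera adjusted p = 5.0e-91 and adjusted p = 0.075 with an estimated correlation). After quantile normalization the median was -2.11, again with all 22 lower. Of 22 genes of glycolysis, 20 fell and 0 rose, the same over the list alone, with a median of -1.15, or -0.61 relative to all genes (camera adjusted p = 3.0e-15 and adjusted p = 0.536 with an estimated correlation). The lactate transporter Slc16a3 stood at 10.5 ± 0.682 against 92.4 ± 14.0 RPKM and Eno2, an enolase, at 2.12 ± 0.129 against 19.24 ± 3.27. After quantile normalization 17 fell and 5 rose, with a median of -0.66.

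Targets of p53 and genes of cholesterol synthesis were higher in the primed knockout libraries. Of 25 p53 targets, 18 rose and 5 fell, the same over the list alone, with a median of 0.67, or 1.20 relative to all genes and 1.23 after quantile normalization, where 20 rose and 5 fell (camera adjusted p = 5.2e-34 and adjusted p = 0.514 with an estimated correlation). Mdm2, the ubiquitin ligase that degrades p53, stood at 213 ± 10.3 against 51.7 ± 3.28 RPKM, Cdkn1a at 189.7 ± 12.3 against 55.4 ± 4.65 and Perp, a membrane protein of cell death and adhesion, at 125 ± 7.67 against 27.5 ± 3.80, while Gdf15, at 0.590 ± 0.152 against 4.36 ± 2.37, and Pmaip1, at 4.61 ± 0.435 against 11.1 ± 3.23, fell. Of 24 genes of cholesterol synthesis, 14 rose and 5 fell, the same over the list alone, with a median of 0.31, or 0.84 relative to all genes and 0.80 after quantile normalization, where 20 rose and 2 fell (camera adjusted p = 8.0e-10 and adjusted p = 0.985 with an estimated correlation). Fry, which tests against no difference, called the p53 targets (adjusted p = 0.0119) but not the genes of cholesterol synthesis (adjusted p = 0.0765). Hsd17b7, an enzyme of the pathway, rose to 15.1 ± 0.508 against 7.33 ± 1.83 RPKM. Insig1 (-0.69) was lower as deposited, but with median centring it stood at 0.0069. Without primed wild-type replicate 1 the cholesterol median was 0.20.

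Ribosomal protein genes fell as deposited, 69 of 75 lower and 0 higher, the same over the list alone, with a median of -0.53, that of all genes (camera adjusted p = 7.2e-15 and adjusted p = 0.985 with an estimated correlation). As the medians are equal, this camera call does not show a larger log2 change than that of all genes. The median level of the ribosomal protein genes in primed wild-type libraries was 850 RPKM. Among genes with a mean log2 RPKM above 8 the median log2 RPKM difference was -0.33. Rpl13a stood at 582 ± 1.498 against 1249 ± 28.6 RPKM and Rpl17 at 395 ± 2.72 against 828 ± 0.317. After quantile normalization 46 fell and 13 rose, with a median of -0.16 (camera adjusted p = 0.00176 and adjusted p = 0.629 with an estimated correlation). After loess normalization the median was -0.33 and the list passed as well (camera adjusted p = 4.3e-07). With median centring the median turned to 0.16 and the list did not pass (camera adjusted p = 0.798), nor did it without primed wild-type replicate 1 (camera adjusted p = 0.364).

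**Figure D2:**
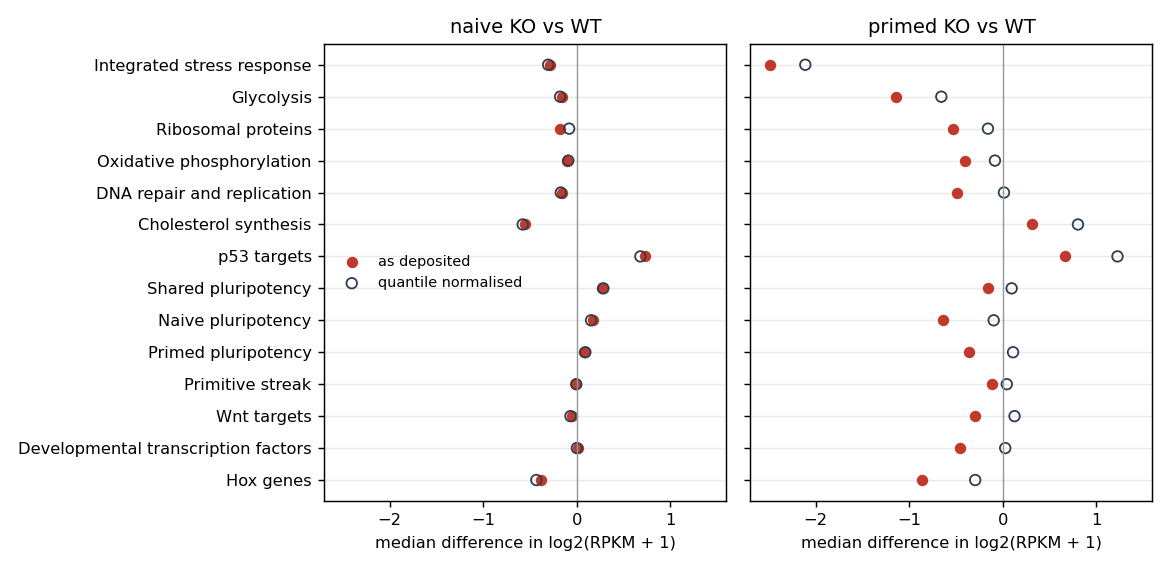
Median difference in log2(RPKM + 1), knockout minus wild type, of 14 gene lists in the naive and primed states, as deposited (filled) and after quantile normalization (open). In the primed state the medians as deposited lie to the left of the normalised ones by amounts that differ between lists. The medians of shared and primed pluripotency, primitive streak, Wnt targets, developmental transcription factors and DNA repair turn from negative to positive, while those of the integrated stress response, glycolysis, cholesterol synthesis and p53 targets keep their sign.

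By the same rule, the genes that rose most in the primed knockout libraries were a Wnt ligand and a target of Wnt signalling. Wnt8a stood at 17.3 ± 1.18 against 0.446 ± 0.0861 RPKM (3.66 ± 0.28, and 4.03 after quantile normalization) and T at 35.5 ± 2.63 against 2.42 ± 0.674 (3.43 ± 0.28, and 4.03), followed by the homeobox gene Nkx2-9 with 3.35, Ltb4r1 with 3.01 and its neighbour Ltb4r2 with 2.47. The largest falls after Trib3 (-5.36 ± 0.15, and -4.90 after quantile normalization) were those of H2-Bl with -5.21, Chac1 with -5.11, the lipoprotein lipase gene Lpl with -4.27 and Nupr1 with -4.23. H2-Bl belongs to a family of near-identical class I genes and its value is uncertain. Of these 10 genes Ltb4r2 had the largest limma adjusted p, 2.3e-17, and 5.5e-07 after quantile normalization.

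Lists of primitive streak genes, Wnt targets and primed pluripotency held strong rises and falls side by side. For the primitive streak 4 of 12 rose and 2 fell, T and Wnt3, at 18.2 ± 1.35 against 4.13 ± 0.934 RPKM, among the first and Fgf8, at 1.69 ± 0.447 against 7.54 ± 2.43, among the second. For Wnt targets 5 of 15 rose and 4 fell (5 and 3 over the list alone), with Wnt8a and T higher and the feedback inhibitor Nkd1, at 0.801 ± 0.0260 against 5.15 ± 1.56 RPKM, and Tcf7, at 22.5 ± 1.26 against 38.6 ± 5.87, lower. For primed pluripotency 7 of 25 rose and 13 fell, with Fst, an Activin antagonist, higher at 11.7 ± 0.250 against 2.95 ± 1.22 RPKM and Fgf15 lower at 2.24 ± 0.00498 against 15.6 ± 3.55. The counts for primitive streak and primed pluripotency were the same over the list alone. These lists and 3 more had medians below 0 that lie above that of all genes, and camera called all 6 higher than other genes. The 3 were surface ectoderm (3 of 17 higher and 5 lower), 2-cell-like genes (0 and 0 of 17) and germline genes (0 and 2 of 20, 0 and 1 over the list alone). In both primed groups 17 of the 17 2-cell-like genes, 19 of the 20 germline genes and 6 of the 12 primitive streak genes had a mean under 1 RPKM. At such levels log2(RPKM + 1) holds any change near 0 and so above a negative median of all genes, and the calls of 2-cell-like and germline genes do not show a rise. In the order given the camera adjusted p of the 6 were 7.9e-05, 3.7e-04, 0.0225, 0.00239, 0.00629 and 0.0294, and adjusted p = 0.985 with an estimated correlation for all. The surface ectoderm median turned to 0.045 without primed wild-type replicate 2. Called higher and lower after quantile normalization were 4 and 1, 8 and 3, 13 and 9, 12 and 3, 2 and 0, and 1 and 3 in the same order, so that the balance of primed pluripotency and surface ectoderm turned. None of the 6 passed there, and the smallest camera adjusted p was 0.122, for surface ectoderm. Without primed wild-type replicate 2 the calls of primed pluripotency, 2-cell-like and germline genes ended as well (camera adjusted p = 0.0571, 0.0682 and 0.122), as did that of germline genes without primed knockout replicate 2 (0.0672). With a pseudocount of 0.1 the germline median was -0.55 in place of -0.078 and its call ended (camera adjusted p = 0.207), while the 2-cell-like median was -0.34 in place of -0.043. Median centring ended the call of primed pluripotency (0.351), and loess normalization ended all 6.

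The primed knockout libraries held less Nanog and more Fgf5 than the wild-type libraries. Nanog stood at 37.1 ± 2.21 against 117 ± 7.79 RPKM (-1.63 ± 0.082, and -1.28 after quantile normalization), Fgf5, a marker of the epiblast, at 18.2 ± 1.45 against 5.15 ± 1.19 (1.65 ± 0.28, and 2.36) and Eomes, a factor of the primitive streak, at 6.59 ± 0.0677 against 1.18 ± 0.165 (1.80 ± 0.28, and 2.41). The naive-state genes Klf4 (-0.87), Zfp42 (-0.78) and Esrrb (-1.51) fell from levels already low in primed wild-type cells, 3.26, 0.831 and 2.53 RPKM, and after quantile normalization the changes were -0.14, -0.45 and -0.93. The neural factors Sox1, at 1.68 ± 0.0424 against 9.63 ± 1.83 RPKM, and Pax6, at 0.960 ± 0.0562 against 9.04 ± 2.14, fell, as did Lefty1 and Lefty2, inhibitors of Nodal, at 20.0 ± 1.75 against 268 ± 27.3 and 1.37 ± 0.123 against 10.3 ± 3.33. Their changes were -1.98, -2.34, -3.67 and -2.22, and -1.23, -1.60, -3.26 and -1.49 after quantile normalization. All of these had limma adjusted p of 1.5e-05, that of Zfp42, or less as deposited.

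Sox2 and Pou5f1 rose in the primed state, as deposited by smaller amounts than Nanog fell. Sox2 stood at 55.5 ± 7.32 against 43.3 ± 6.19 RPKM (0.35 ± 0.098, limma adjusted p = 8.7e-04) and Pou5f1 at 658 ± 13.1 against 582 ± 31.3 (0.18 ± 0.072, adjusted p = 0.022). After quantile normalization the rises were 0.78 for Sox2 (adjusted p = 4.8e-06) and 0.55 for Pou5f1 (adjusted p = 4.8e-07), and with median centring 1.05 and 0.87. As deposited, Sox2 did not pass without primed knockout replicate 1 (adjusted p = 0.158), and its change was 0.21 without primed wild-type replicate 1. The Pou5f1 call ended when any 1 of 4 libraries was left out, with the largest adjusted p, 0.403, without primed wild-type replicate 1. H2afz, the gene of the histone variant H2A.Z that INO80 acts on, stood at 347 ± 22.2 against 402 ± 26.2 RPKM (-0.21 ± 0.074, adjusted p = 0.00903), but at 0.079 after quantile normalization and 0.48 with median centring, and it did not pass without primed wild-type replicate 2 (adjusted p = 0.283). Otx2 (14.0 against 17.1 RPKM), Dnmt3b (172 against 182), Gata4 (1.12 against 1.902) and Gata6 (0.125 against 0.1998) did not pass as deposited, and the sign of each turned from negative to positive after quantile normalization, where Otx2, Dnmt3b and Gata4 passed (adjusted p = 0.00265, 0.00806 and 0.0273).

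In all, 8517 of 13428 genes passed in the primed state at a limma adjusted p under 0.05, 559 higher and 7958 lower, of which 130 and 2763 changed 2-fold or more. The median of all genes was -0.53 as deposited. The shift differed with the level, with a median log2 RPKM difference of -1.03 among genes with a mean log2 RPKM of 0 to 2, -0.78 for 2 to 4, -0.49 for 4 to 6, -0.23 for 6 to 8 and -0.33 above 8. The values relative to all genes given above therefore remove it only in part. After quantile normalization, with a median of 0.027, 9936 genes passed, 5288 higher and 4648 lower, and with median centring 8743 passed, 5580 higher and 3163 lower. Both scalings set the libraries level by construction, so these balances do not show whether the surplus of lower genes is due to the deposited scale. Of the genes called as deposited, 558 were higher and 4617 lower also after quantile normalization, and 879 of those lower were then called higher. Among 2-fold changes, 467 higher and 615 lower passed after quantile normalization, and 130 and 615 of them on both scales. As deposited with a pseudocount of 0.1, 198 called genes were higher and 4054 lower by 2-fold or more. With 1 library left out the count as deposited ran from 5539 to 9960, with 324 to 805 higher and 5137 to 9535 lower, and with 96 to 179 and 1852 to 3980 at 2-fold or more.

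**Figure D3:**
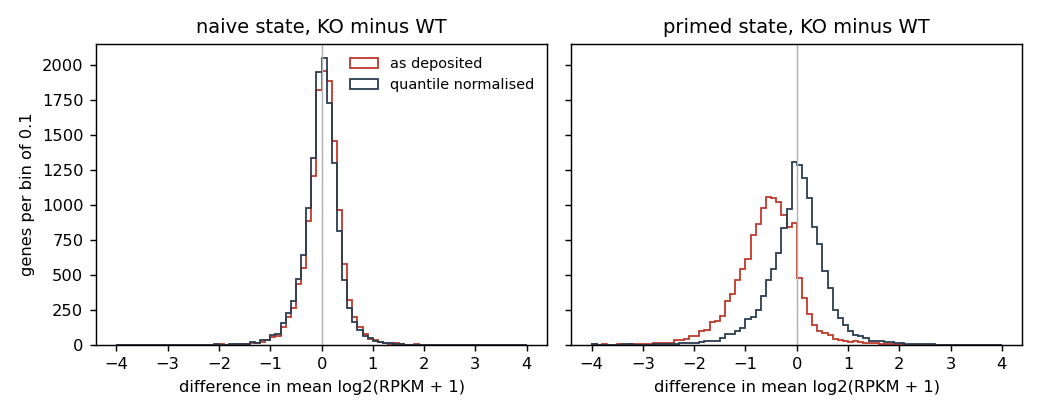
Number of genes per bin of 0.1 by their difference in mean log2(RPKM + 1), knockout minus wild type, in the naive and primed states, as deposited (red) and after quantile normalization (blue), with values beyond 4 drawn in the outermost bins. The naive distributions nearly coincide, and the primed distribution as deposited lies to the left of 0 while the normalised one is centred near it.

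The effect of the knockout differed between the states for genes of cholesterol synthesis, the stress response and glycolysis. Of 24 genes of cholesterol synthesis, 18 had a higher and 0 a lower effect in the primed state, the same over the list alone, with a median difference of the effects, primed minus naive, of 0.75 (camera adjusted p = 1.4e-38 and adjusted p = 0.5 with an estimated correlation). The effect on Msmo1, a sterol enzyme, was 1.76 higher in the primed state. For the integrated stress response all 22 genes had a lower effect in the primed state, also over the list alone, with a median difference of -2.28 (camera adjusted p = 6.3e-83 and adjusted p = 0.0896 with an estimated correlation). Trib3 differed by -5.29 ± 0.21, Chac1 by -4.44 ± 0.32 and Ddit3, the gene of CHOP, by -3.86 ± 0.24.

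For glycolysis 16 of 22 had a lower effect in the primed state and 0 a higher one, 18 and 0 over the list alone, with a median difference of -0.88 (camera adjusted p = 6.0e-10 and adjusted p = 0.976 with an estimated correlation), led by the glucose transporter Slc2a3 (-2.43) and Pfkp (-2.36), a phosphofructokinase. With median centring that list did not pass (camera adjusted p = 0.061). For p53 targets 9 of 25 had a higher and 6 a lower effect, the same over the list alone, with a median difference of 0.15, or 0.74 relative to all genes, and a mean of -0.016 (camera adjusted p = 2.3e-09 and adjusted p = 0.976 with an estimated correlation). The call is one against other genes, and fry, which tests against no difference, did not call the list (adjusted p = 0.307). Cdkn1a (1.39) and Perp (1.19) differed one way and Pmaip1 (-2.34) and Gdf15 (-1.95) the other. That median was 0.085 without primed knockout replicate 1, 0.072 without primed wild-type replicate 1 and 0.23 without replicate 2. After quantile normalization the members with a higher and a lower effect were 24 and 0 for cholesterol synthesis, 0 and 22 for the stress response, 2 and 14 for glycolysis and 19 and 4 for p53 targets. All 4 lists passed, with medians of 1.15 for cholesterol synthesis, -1.85 for the stress response, -0.44 for glycolysis and 0.73 for p53 targets. None of the 4 passed there with an estimated correlation (camera adjusted p = 0.0685, 0.0685, 0.789 and 0.6 in the same order).

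Camera also called the lists of primitive streak genes, Wnt targets, germline genes, 2-cell-like genes and developmental transcription factors higher than other genes, and Nodal and Activin targets lower (adjusted p = 1.7e-07, 6.8e-06, 3.5e-05, 0.00118, 0.0215 and 0.0411, and adjusted p = 0.976 with an estimated correlation for all). The median differences of these lists were 0.17, -0.017, 0.067, 0.042, -0.37 and -0.72 in that order. For developmental transcription factors and Wnt targets the median is below 0, so these calls do not show a higher effect in the primed state. The counts of members with a higher and a lower effect in the 6 lists were 5 and 2 of 12, 5 and 3 of 15, 3 and 2 of 20 (2 and 2 over the list alone), 0 and 0 of 17, 4 and 23 of 64, and 1 and 7 of 12, otherwise the same over the list alone. For germline and 2-cell-like genes, nearly all under 1 RPKM in both primed groups, the primed effect is held near 0 and the median of all genes lies at -0.59, so these calls do not show a higher effect. In the same range in both primed groups were 6 of the 12 primitive streak genes, 4 of the 15 Wnt targets and 18 of the 64 developmental transcription factors. The counts of members with a higher and a lower effect became 6 and 2, 9 and 3, 9 and 3, 7 and 3, 22 and 25, and 4 and 7 in the same order after quantile normalization. None of these 6 passed there, and the smallest camera adjusted p was 0.122, for Wnt targets, and none did after loess normalization. The call of developmental transcription factors also ended without naive wild-type replicate 1 or naive knockout replicate 2 (camera adjusted p = 0.352 and 0.0518), and that of Nodal and Activin targets without naive wild-type replicate 1 or 2 (0.104 and 0.113). Median centring ended both (0.634 and 0.561), and a pseudocount of 0.1 that of Nodal and Activin targets (0.0594). In the last list Eomes (1.68) went against Lefty1 (-3.22) and Foxh1 (-1.76), a partner of the Smad proteins.

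Of single genes, T had the largest positive difference between the states (4.31 ± 0.40), followed by Wnt8a (2.55), Stra8 (2.30), Cxx1c (2.28) and Sohlh2 (2.21). Stra8 and Sohlh2 fell in the naive state and were near 0 in both primed groups, at 0.0315 against 0.185 and 0.00939 against 0.0499 RPKM, so that their primed effect on this scale is held near 0. Their ratios of mean RPKM, knockout over wild type, were alike in both states, 0.15 in the naive and 0.17 in the primed state for Stra8 and 0.17 in the naive and 0.19 in the primed state for Sohlh2, so a differing effect is not shown for them. Cxx1c has near-identical copies, so its value is uncertain. After Trib3 the largest negative differences were those of H2-Bl (-4.53), Chac1, Tmem63a (-4.04) and Ddit3. The effect also differed for Nanog (-1.68), Esrrb (-1.65), Zfp42 (-0.96), Fgf5 (1.71), Sox1 (-1.75), Pax6 (-2.34), Klf4 (-0.88) and Ino80 (-0.91 ± 0.26), with limma adjusted p of 0.00203, that of Ino80, or less. Fgf5 and Pax6 lay under 1 RPKM in both naive groups, and Zfp42 in both primed groups. At such levels log2(RPKM + 1) shrinks the effect in that state, so a naive effect on Fgf5 and Pax6 could hardly be seen. Klf4 did not pass after quantile normalization (-0.12, adjusted p = 0.0952) or without naive knockout replicate 1 (adjusted p = 0.0634), and the Ino80 difference was -0.18 after quantile normalization (adjusted p = 0.0146) and, as given above, did not pass with median centring. Pou5f1, Sox2, Otx2, Dnmt3b, Gata4, Gata6 and H2afz did not pass as deposited, with limma adjusted p from 0.0606 for Gata6 to 0.708 for H2afz. After quantile normalization Pou5f1 (0.37, adjusted p = 7.0e-05), Sox2 (0.46, 0.00118), Gata4 (0.33, 0.0222) and Gata6 (-0.55, 0.00767) passed, and the sign of Otx2, Gata4 and H2afz turned. With median centring Sox2, Otx2, Dnmt3b and Gata4 passed, the largest adjusted p being 0.0418, for Dnmt3b.

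In all, 6658 genes passed the test of the difference (limma adjusted p under 0.05), 290 with a higher and 6368 with a lower effect in the primed state, around a median of -0.59 over all genes, and 109 and 2895 of them differed 2-fold or more. The count was 3457 without primed knockout replicate 2, 4389 without primed knockout replicate 1, 3509 without naive knockout replicate 1 and 4029 without naive knockout replicate 2. With 1 library left out 148 to 448 had a higher and 3278 to 9014 a lower effect, 75 to 176 and 1852 to 4295 at 2-fold or more. After quantile normalization 8651 passed, 4557 higher and 4094 lower (413 and 520 at 2-fold or more), with 290 higher and 3990 lower on both scales and 53 turned from lower to higher. As deposited with a pseudocount of 0.1, 112 higher and 3488 lower effects differed 2-fold or more.

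Part of the change was shared between the states. Across the 13428 genes, the naive and primed effects correlated with Pearson r = 0.343 and Spearman rho = 0.327, from comparisons that share no library, and genes are not independent replicates. Of the 816 genes higher in the naive and the 559 higher in the primed state, 209 were the same, where 33.97 would be shared by independent lists, and of the 786 and 7958 lower ones 628 were the same, where 466 would be (two-sided Fisher's exact test, p = 4.0e-115 and 1.1e-36, unadjusted, 2 tests, over genes as units). Of the 816 genes, 249 were lower in the primed state, more than were shared, where 484 would be, and 18 of the 786 were higher there, where 32.7 would be. After quantile normalization 2582 higher and 2116 lower genes were shared, where 1685 and 1276 would be, and after loess normalization 2297 and 2226, where 1446 and 1391 would be, so the excess in proportion depends on the scale. Suclg2 and Parp2, taken up in the primed state after their values were seen, were lower in the libraries labelled knockout in both states. Suclg2 stood in the primed state at 7.47 against 42.5 RPKM and Parp2 at 4.70 against 49.3, changes of -2.36 ± 0.17 and -3.14 ± 0.19 (limma adjusted p = 3.3e-41 or less, and 3.3e-08 or less after quantile normalization). Parp2 lies next to Rpph1, and how reads shared by such neighbours were counted is not stated, so its value is uncertain.

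No test was made between naive and primed libraries, because the deposited values of each state were scaled apart, so the levels that follow are descriptive. Of 25 genes of the naive state all 25 had a lower mean in primed than in naive wild-type libraries, and 24 of 25 genes of the primed state had a higher one. In the wild-type libraries Zfp42 stood at 226 and 0.831 RPKM in the naive and the primed state, Esrrb at 181 and 2.53, Otx2 at 0.297 and 17.1 and Dnmt3b at 18.1 and 182. In the libraries labelled knockout Zfp42 stood at 256 and 0.0667, Esrrb at 199 and 0.231, Otx2 at 0.363 and 14.0 and Dnmt3b at 20.7 and 172. The integrated stress response had a median log2 difference, primed minus naive, of 1.61 in wild-type and -0.54 in knockout-labelled libraries, where that of all genes was 0.32 and -0.26.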

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

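The tests of the 3 patterns below were all chosen after the result was seen, while the difference of effects between the states was a planned comparison. That difference, primed minus naive, passed as deposited and after quantile normalization for 4 lists and for 30 of 38 named genes. None of the 4 lists passed camera with an estimated correlation (smallest adjusted p = 0.0896 as deposited and 0.0685 after quantile normalization). With median centring glycolysis did not pass (camera adjusted p = 0.061). For cholesterol synthesis the median difference was 0.75 (1.15 after quantile normalization), for p53 targets 0.15 (0.73, a call against other genes that fry, against no difference, did not make, adjusted p = 0.307), for glycolysis -0.88 (-0.44) and for the integrated stress response -2.28 (-1.85). The effect was higher in the primed state for T 4.31, Wnt8a 2.55, Cxx1c 2.28, Msmo1 1.76, Cdkn1a 1.39, Perp 1.19, Eomes 1.68, Fgf5 1.71 and Vim 1.38. It was lower for Ino80 -0.91, Trib3 -5.29, H2-Bl -4.53, Chac1 -4.44, Tmem63a -4.04, Ddit3 -3.86, Pmaip1 -2.34, Gdf15 -1.95, Slc2a3 -2.43, Pfkp -2.36, Lefty1 -3.22, Foxh1 -1.76, Nanog -1.68, Zfp42 -0.96, Esrrb -1.65, Sox1 -1.75, Pax6 -2.34, Cyr61 -3.07 and Ctgf -2.44. The Ino80 difference was only -0.18 after quantile normalization and did not pass with median centring. Fgf5 and Pax6 lay under 1 RPKM in both naive groups, and Zfp42 in both primed groups, where the log scale shrinks the effect. Stra8 2.30 and Sohlh2 2.21 also passed, but both lie under 1 RPKM in both primed groups, where the log scale holds the effect near 0. Their ratios of mean RPKM, knockout over wild type, were alike in the naive and primed states (0.15 and 0.17 for Stra8, 0.17 and 0.19 for Sohlh2), so a differing effect is not shown for them.

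Most called genes were lower in the primed knockout libraries, 7958 against 559. The gap between the medians of the 2 primed wild-type libraries, 0.375, was 0.541 times the gap between genotypes, 0.694. The authors' scaling may account for the surplus of lower genes, and this ratio does not decide it. Whether that scaling used the spike-ins is not stated. If it did, the surplus could reflect less RNA per knockout cell, which quantile and loess normalization would remove. With 0 spike-in rows, less RNA per knockout cell and the scaling cannot be told apart.

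All 22 genes of the integrated stress response were lower in the primed knockout libraries. The scaling as the whole cause is argued against by the median after quantile normalization, -2.11, with all 22 still called lower. A single stressed wild-type library is argued against by the medians of the 2 primed wild-type libraries, which differed by 0.0923 after quantile normalization. In wild-type libraries the list lay 1.29 higher in the primed than in the naive state relative to all genes, and -0.28 in libraries labelled knockout. A loss of the stress response through loss of INO80 and another growth state of both primed wild-type cultures, in density or medium, cannot be told apart without matched cultures.

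In the naive state Ino80 was not lower in the libraries labelled knockout while p53 targets were higher. A swap of naive labels would turn the correlation of the effects of the states, which was 0.343 and at least 0.273 with any library left out, and this argues against a swap if effects are shared between states. The Ino80 difference of -0.020 is a value of the whole gene, so a transcript without the deleted part may still be counted, and an incomplete deletion may leave it unchanged as well. These cannot be told apart without values per exon. If the deletion was incomplete, the naive changes and the differences between the states do not measure the effect of a full loss. The p53 target median of 0.73 has no library of treated cells without the conditional allele beside it. Loss of INO80 and an effect of 4-OHT or the recombinase on p53 targets therefore cannot be told apart. The same holds for the primed median of p53 targets, 0.67.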

How the results depend on the processing

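Loess normalization was the only test here chosen after the data were seen. Of named genes other than Ino80, called or not, 51 of 52 in the naive state, 62 of 62 in the primed state and 36 of 37 for the difference kept direction and side of the threshold with a pseudocount of 0.1. With median centring 48, 51 and 31 did, and with the replicate number as a term 49, 62 and 37. After quantile normalization 45, 57 and 32 did, and with every library left out in turn 42, 56 and 34. The number of genes called in the naive state, 1602, was 4456 with median centring, 7967 after quantile normalization, 7719 after loess normalization, 2526 from the naive libraries alone and 908 without a variance trend. Rescaled values also had a smaller residual spread. The cause was not tested. With 1 library left out it ran from 552 to 2946, from 5539 to 9960 in the primed state and from 3457 to 9269 for the difference. The number of lists called in the naive state, 14, was 7 with median centring, 0 with an estimated correlation and 0 with fry. In the primed state, 11 in the main analysis, it was 5 after quantile and 5 after loess normalization, 0 with an estimated correlation and 23 with fry, of which 5, 5, 0 and 4 were among the 11 in the same direction. For the difference, 10 in the main analysis, the numbers were 4, 5, 0 and 6, with 4, 4, 0 and 4 among the 10, or 11 to 16 with 1 library left out, with 8 to 10 among the 10. The estimated correlation widens the null of camera by construction, and fry tests a list against 0 and not against other genes. For the other changes the cause was not tested. Ino80 stood at -0.099 in the naive state after loess normalization (limma adjusted p = 0.0461), and its difference between states at -0.16 with median centring (adjusted p = 0.214). The cause was not tested. The correlation of the effects of the states, 0.343, was 0.389 with a filter of 5 RPKM, 0.387 after quantile and 0.380 after loess normalization, and 0.273 to 0.371 with 1 library left out, lowest without naive wild-type replicate 1. In the primed state Insig1 turned to 0.0069 and H2afz to 0.48 with median centring, and H2afz to 0.079 after quantile normalization. The cause was not tested. As a replicate block, the replicate number left 1120 genes in the naive state, 7622 in the primed state and 5133 for the difference. Residuals of like-numbered knockout and wild-type libraries correlated by 0.314 in the naive and -0.0356 in the primed state as deposited, and by -0.0411 and -0.122 after quantile normalization. Quantile normalization also removes shifts that whole libraries share, so these values do not decide whether the numbers pair the libraries. Centring on spike-ins and the planned tests between the states were not run, the first for want of spike-in rows and the second because the states were scaled apart. Depth is unknown, so what it limits cannot be said.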

Other observations

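Single imprinted genes changed strongly although their list did not pass camera. H19, a maternally expressed RNA, rose in the naive state to 4.48 ± 0.259 against 1.35 ± 0.531 RPKM and Slc38a4 fell to 31.1 ± 0.589 against 60.2 ± 0.0611. H19 went the other way in the primed state, taken up after its values were seen, at 13.9 ± 0.617 against 72.7 ± 6.62 RPKM, a change of -2.30 ± 0.22 (limma adjusted p = 1.1e-24), or -1.82 after quantile normalization. In the primed state Peg10, at 82.5 ± 4.11 against 31.3 ± 3.72, and Magel2, at 20.4 ± 1.66 against 7.50 ± 1.66, rose, while the adaptor gene Grb10, at 3.80 ± 0.185 against 63.1 ± 9.34, and Phlda2, at 0.559 ± 0.133 against 7.15 ± 1.72, fell. Of the matrix and cytoskeleton genes, Tagln and Cyr61 rose in the naive state by 1.38 and 1.14. Among primed libraries Vcan and Vim rose by 1.70 and 1.24, and Ctgf and Cyr61 changed by -1.99 and -1.93. The largest limma adjusted p of these 11 genes was 8.4e-06, that of Magel2.

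The class I genes H2-K1, at 13.2 ± 0.853 against 92.8 ± 14.6 RPKM, and H2-D1, at 1.43 ± 0.210 against 9.69 ± 1.77, fell in the primed state, while Tap1, which loads them with peptide, rose to 20.2 ± 1.51 against 7.40 ± 1.37. Class I genes are closely related in sequence, so their values are uncertain. Of the other INO80 subunits, Ino80b was higher in both states, by 0.67 in the naive and 0.48 in the primed state. Its calls ended without naive knockout replicate 1 (limma adjusted p = 0.162) and without primed knockout replicate 1 (0.177), and its primed change was 0.29 without primed wild-type replicate 1. Ino80c rose in the primed state by 0.52, a call that ended without primed knockout replicate 1 (limma adjusted p = 0.108) and without primed wild-type replicate 1 (0.0636), where the change was 0.29, and Actr5 changed by -1.18. After quantile normalization Ino80b rose by 0.61 and 1.08 and Ino80c by 1.19, and Actr5 changed by -0.52.

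Camera tests a list against other genes, and in the primed state 559 of all 13428 genes were called higher and 7958 lower. Fry, which tests against 0, called Polycomb complexes and H3K4 methylation, among others, lower there (adjusted p = 0.0284 and 0.0241). Some lists called in the naive state did not pass camera in the primed state (adjusted p of 0.102 or more). There 0 and 16 (after quantile normalization 4 and 13) of 23 Hox genes were called higher and lower. Of 35 DNA repair and replication genes the counts were 0 and 23 (15 and 15). For G2 and mitosis they were 0 and 23 (8 and 16) of 29. For oxidative phosphorylation and shared pluripotency they were 8 and 47 (27 and 35) of 76 and 3 and 8 (9 and 5) of 20. Of 64 developmental transcription factors, 5 were called higher and 4 lower in the naive and 6 and 30 in the primed state. After quantile normalization the counts were 12 and 18 in the naive and 17 and 21 in the primed state. For 21 of the 41 lists, Polycomb complexes and H3K4 methylation included, camera called no difference from other genes in any comparison, with the smallest adjusted p at 0.13 in the naive state, 0.102 in the primed state and 0.0659 for the difference. Their members called higher and lower, first in the naive and then in the primed state, as deposited and in brackets after quantile normalization, were 1 and 0 then 2 and 7 (7 and 3 then 8 and 2) of 14 for the other subunits of INO80, 1 and 2 then 0 and 13 (8 and 4 then 8 and 4) of 18 for H2A.Z and its exchange factors, 2 and 0 then 0 and 10 (9 and 3 then 8 and 7) of 17 for other remodellers, 2 and 1 then 0 and 14 (13 and 6 then 5 and 11) of 25 for naive pluripotency, 1 and 2 then 0 and 9 (2 and 8 then 0 and 6) of 16 for mesoderm and 2 and 1 then 1 and 6 (8 and 4 then 6 and 4) of 15 for endoderm. The counts were 3 and 0 then 2 and 9 (6 and 4 then 8 and 7) of 19 for neuroectoderm, 1 and 1 then 2 and 5 (5 and 4 then 5 and 3) of 13 for trophoblast, 4 and 3 then 2 and 20 (11 and 12 then 14 and 14) of 32 for Polycomb complexes, 1 and 2 then 0 and 16 (8 and 7 then 8 and 4) of 19 for H3K4 methylation, 2 and 1 then 0 and 7 (6 and 4 then 10 and 2) of 14 for DNA methylation, 2 and 1 then 1 and 6 (3 and 4 then 3 and 4) of 11 for BMP targets and 2 and 1 then 0 and 7 (3 and 4 then 3 and 5) of 11 for Notch and Hedgehog targets. They were 5 and 4 then 3 and 15 (10 and 9 then 11 and 11) of 25 for imprinted genes, 0 and 1 then 1 and 9 (0 and 2 then 1 and 5) of 11 for fibroblasts, 1 and 0 then 0 and 0 (2 and 2 then 4 and 0) of 7 for blood and endothelium, 1 and 1 then 6 and 11 (4 and 4 then 10 and 6) of 20 for heat shock and folding, 0 and 1 then 1 and 7 (3 and 5 then 4 and 5) of 12 for interferon response, 3 and 0 then 4 and 9 (5 and 1 then 7 and 6) of 19 for replication histones, 10 and 11 then 8 and 61 (15 and 17 then 29 and 18) of 100 for small nuclear and nucleolar RNAs and 2 and 2 then 1 and 6 (4 and 4 then 4 and 5) of 9 for nuclear long RNAs.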
